A study of Mus musculus with 5 samples.

How the data were processed

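RNA of the right brain hemisphere of 5 male C57BL/6 mice aged 5 months was measured, with 1 library per sample, made with an mRNA library kit per the labels' protocols. Per the submitters' processing notes, CASAVA 1.7, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the mouse genome build GRCm38. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. The deposited count table holds whole-number counts per Ensembl gene for 47729 genes and 5 libraries, not normalized and not pooled. The deposited RPKM table was made by the authors from these counts, as the values show.

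The deposited RPKM values were tested against the counts before use. With the 5 library totals taken in turn down the rows of the table, all 117232 nonzero entries were recovered (100.0%, tolerance 0.0011 RPKM plus a relative 0.0002), whereas with each library's own total 21.9% were. Both shares use the gene length recovered with totals in turn, which favours that rule. A check without a fixed length used 7363 genes with an RPKM of at least 5 in all libraries. The length implied by each library had a median coefficient of variation of 0.00178% with totals in turn and 10.7% with own totals. Of all entries, 80% were thus divided by the total of another library, and the largest ratio of totals was 1.18. For 5142 genes with a mean RPKM of at least 10, the median SD of log2 values between animals was 0.158 in the deposited table, 0.0648 after division by each library's own total and 0.0656 for TMM-scaled CPM (counts scaled to library depth). RPKM values printed here were therefore recomputed from the counts with each library's own total and the gene length recovered from the tables, and the deposited values, which the design had named for the gene pairs, serve as an alternative. The recovered length equals the union of annotated exons for 55.9% of 14068 genes and lies within 10% of it for 81.2%.

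Gene symbols and positions on GRCm38 were taken from the GENCODE annotation for 47224 of the genes by Ensembl ID. Differences between libraries were larger than counting noise in all 10 pairs of libraries (chi-square per degree of freedom 2.28 to 3.89), which excludes libraries that differ by counting noise alone but not a further library made from the same RNA. Depth ran from 13184234 to 15570064 counts. Reads without molecular identifiers are not independent molecules, so depth sets counting error only.

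The tests, the gene lists and pairs and the rule for named genes were chosen before the data were examined. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, estimateDisp, robust glmQLFit with legacy settings and an intercept only), which left 14770 genes. Each gene's quasi-dispersion was divided by its abundance trend and the ratio compared with an F distribution on 4 residual and 15.3 prior degrees of freedom, one-sided in each tail, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene past the upper tail is called more variable, or called. Range folds and log2 deviations use TMM-scaled log2 CPM with a prior count of 2.

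Of 61 fixed lists of cell type, region, state and pathway genes, 51 had at least 4 tested members. For each, the SD over animals of the mean log2 deviation of its members was ranked among 10000 random lists of the same size matched on abundance in 20 bins, one-sided, with adjustment over the lists, and the median ratio to the trend was ranked in the same way. The smallest permutation p that 10000 lists give is 0.0001. The p-values of single members from the variability test were also adjusted over their own list alone. That adjustment was not extended over the 61 lists, so such counts hold the threshold within a list only. Of the fixed symbols, 1 (Ahsp) was not matched. For 28 fixed pairs the log2 ratio of RPKM plus 0.1 was taken within each animal and tested with an exact two-sided sign-flip test over 32 sign patterns. Sequence shared with other genes is the percentage of words of 50 bases of a gene's transcripts, taken every 5 bases, that occur in transcripts of other annotated genes, and 20% or more was taken as uncertain.

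Genes were named by a fixed rule. It takes the 20 nuclear genes with the highest mean RPKM and a mean count of at least 100, the 3 most abundant members of each list, the 25 genes with the smallest adjusted p for variability, the called members of each list (at most 4), the 10 steadiest genes with a CPM of at least 50, both genes of each pair and 4 leading members of each list that moved together. Where room was short, the first of each part were named and the rest counted. Genes named outside this rule, among them Gabra6, Pcp2, Xist, Rpl19, Mki67, Dcx, Lcn2, Prl, Slc6a4 and the mitochondrial genes listed at 0, were chosen after their values were seen.

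The variability test was tested on simulated counts for the 14770 genes. Genes changed in 1 or 2 animals by 1.5-fold, 2-fold and 4-fold were called in 42.4%, 72.8% and 98.0% of cases, and 4.82% of the genes called were unchanged. The simulated spread was drawn from the fitted trend and prior that the test assumes. The 4.82% therefore does not show how well real genes follow that prior. On simulated lists, 0 of 255 unchanged lists were called as moving together and 2 as having variable members, and lists raised 1.1-fold and 1.2-fold in 1 or 2 animals were called as moving together in 56.0% and 84.0% of cases. The simulated genes were drawn independently of each other. The share of false list calls among correlated genes, as in real libraries, was therefore not tested.

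Alternatives covered other scalings (DESeq2 1.42.0 size factors, upper quartile, total counts), no filter and a stricter filter, a prior that is not robust, fits without mitochondrial genes, leaving out each library in turn, limma 3.58.1 on log2 values, DESeq2 dispersion outliers, a threshold of 0.01, other prior counts, pseudocounts and abundance bins, medians over members, a gene length correction, and counts without length for the pairs. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for lists, pairs and figures. No column of the tables was left out.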

Results

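The right brain hemisphere of 5 male C57BL/6 mice, an inbred laboratory strain, was profiled by mRNA sequencing at an age of 5 months, with 1 library per sample. The labels place all 5 samples in 1 group, so no condition was compared with another. The comparisons that this design allows are of genes with each other within a brain and of the samples with each other. The sample titles carry different numbers but do not state that each sample is a separate animal, which is how they are called here, so p-values measure only the spread between these samples, which may be technical. Replicate numbers were given in accession order and only name the animals. Library depth was 13382731, 14884123, 14200432, 15570064 and 13184234 counts in animals 1 to 5. Of 47729 annotated genes, 28276 had at least 1 count, and 13039 reached a mean RPKM (reads per kilobase of gene length, scaled to library depth) of 1, among them 12062 protein-coding genes. Mitochondrially encoded genes took 3.68% ± 0.205 of the counts, with 6 of them listed at 0 and so not part of this share, and the 100 most abundant genes took 15.9% ± 0.210. Values after ± are the SD over the 5 animals (n = 5) throughout.

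Fth1 (ENSMUSG00000024661, GRCm38 chromosome 19, 9980598 to 9985098), the heavy chain of ferritin, had the highest mean of the nuclear genes at 1486 ± 81.7 RPKM. Cpe (ENSMUSG00000037852, chromosome 8, 64592542 to 64693054), a carboxypeptidase that trims prohormones, followed among the protein-coding genes at 1080.1 ± 24.1. Cst3, the secreted protease inhibitor cystatin C, stood at 695 ± 11.9, Sparcl1 at 679 ± 25.7 and the lysosomal precursor gene Psap at 604 ± 7.23. Calm3, which encodes calmodulin, reached 548 ± 19.0, and the sodium pump subunit gene Atp1b1 519 ± 17.0. App (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766), the amyloid precursor protein, stood at 545 ± 6.29, and Apoe, the main lipid carrier of the brain, at 511 ± 14.9. Of the 20 nuclear genes with the highest means, 4 are processed pseudogenes (Gm12328, Gm37421, Gm14000 and Gm44389), of which Gm12328 shares 20% of its sequence with other annotated genes and is uncertain. In all, 340 genes passed a mean of 100 RPKM.

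Markers of every major brain cell type were measured. Excitatory neurons were represented by Nrgn (561 ± 60.2 RPKM), a calmodulin-binding protein of dendrites, Slc17a7 (382 ± 21.99), which loads glutamate into synaptic vesicles, and Camk2a (364 ± 21.6). Among markers of inhibitory neurons, the neuropeptide gene Sst reached 244 ± 15.7, and Gad1, which makes the transmitter GABA, 56.5 ± 1.02. The presynaptic gene Snap25 stood at 369 ± 15.5. Astrocytes were represented by the glutamate transporter Slc1a2 (302 ± 6.82), Aldoc (261 ± 17.2) and Clu (213 ± 2.88), and oligodendrocytes by the myelin genes Mbp (288 ± 29.7) and Mobp (117 ± 8.10). The microglial genes Ctss and C1qb stood at 45.7 ± 2.13 and 40.8 ± 2.67. The endothelial genes Slc2a1, Itm2a and Cldn5 lay between 23.9 and 31.9. Ttr, the thyroid hormone carrier made by the choroid plexus, stood at 480.4 ± 18.5. Among region markers, striatal Penk reached 145 ± 10.8 and Ppp1r1b 88.7 ± 10.3, hippocampal Wfs1 42.7 ± 1.49, cortical Lamp5 43.7 ± 3.83 and thalamic Prkcd 18.7 ± 0.842. The hypothalamic genes Avp, Pmch and Hcrt had means of 28.1 ± 8.67, 12.1 ± 1.99 and 8.22 ± 1.21. All 4 Y-linked genes of the sex check were detected, led by Ddx3y at 9.90 ± 1.80, whereas Xist, the X-inactivation transcript of females, stood at 0.0178 ± 0.00500.

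Related genes that carry out neighbouring tasks were compared within each animal, and most pairs held 1 order throughout. The vesicular glutamate transporter gene Slc17a7 exceeded Slc17a6 by 18.0-fold (log2 ratio 4.17 ± 0.27). The neuronal chloride exporter Slc12a5 exceeded the importer Slc12a2 by 5.38-fold, the astrocytic transporter Slc1a2 exceeded Slc1a3 by 5.47-fold, and proenkephalin (Penk) exceeded prodynorphin (Pdyn) by 9.03-fold. The neurotrophin receptor gene Ntrk2 was higher than Ntrk3 by 6.94-fold, and the de novo DNA methyltransferase Dnmt3a than Dnmt3b by 29.7-fold. The NMDA receptor subunit gene Grin2a lay below Grin2b (log2 ratio -0.81 ± 0.074), the mineralocorticoid receptor Nr3c2 below the glucocorticoid receptor Nr3c1 (-0.91 ± 0.083) and the cannabinoid receptor Cnr1 below the GABA receptor subunit Gabbr1 (-1.82 ± 0.049). Gad1 exceeded Gad2 by 1.09-fold, a small difference that kept its sign in all 5 animals. In all, 26 of the 28 pairs had the same sign in all 5 animals, each with an exact two-sided sign-flip p of 0.0625, the smallest that 5 animals allow, so no pair can pass 0.05. Among the 2 exceptions was Aldoc against Aldoa, higher in 3 of 5 animals (exact p = 0.438). On counts without a length adjustment the order turned for 5 pairs, among them Gria2 against Gria1 (log2 ratio -1.17 with and 0.19 without), Slc2a3 against Slc2a1 (-0.31 and 0.74), Drd1 against Drd2 (-0.42 and 0.76) and Aldoc against Aldoa (0.036 and -0.17), and the log2 ratio was 3.30 for Slc17a7, 3.07 for Slc1a2, 2.36 for Penk and 1.68 for Ntrk2. Dnmt3b stood at 0.186 RPKM, so its ratio to Dnmt3a rests on the value added to each RPKM (log2 4.89 with 0.1 added, 2.97 with 1 added and 7.21 on counts without length). Eno1 shares 47.5% of its sequence with other genes, so the 11.2-fold excess of the neuronal enolase Eno2 over it is uncertain.

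**Figure D1:**
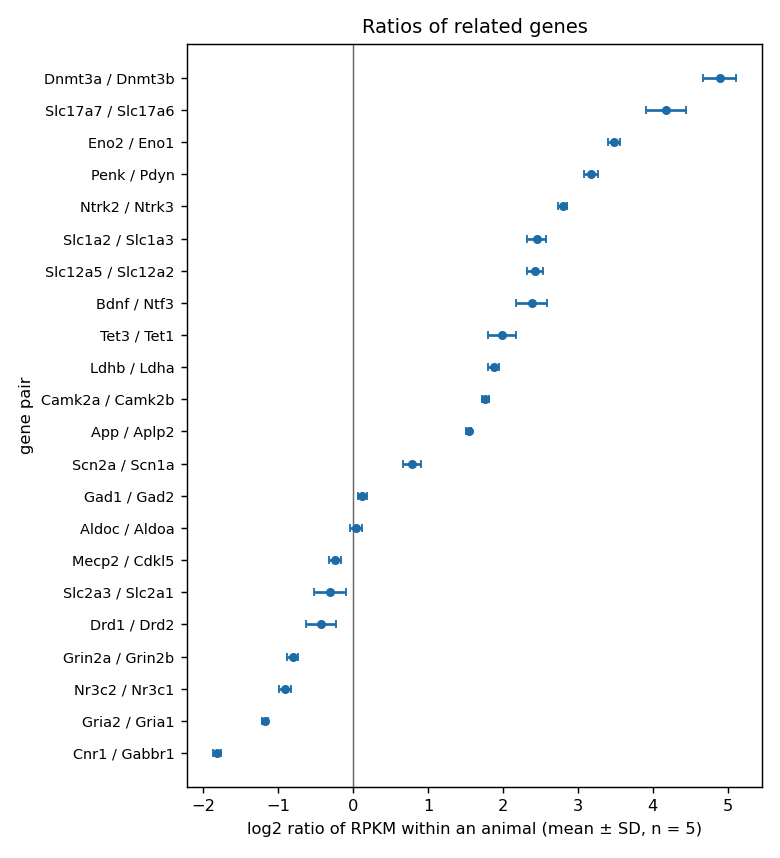
Within-animal log2 ratio of RPKM for pairs out of the 28 fixed gene pairs, with points at the mean and bars of 1 SD over 5 animals. Slc17a7 against Slc17a6 lies at 4.17 and Cnr1 against Gabbr1 at -1.82, while the bar of Aldoc against Aldoa crosses zero.

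Several genes that every brain cell uses were listed at 0 or at low values. The mitochondrially encoded respiratory genes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l had a count of 0 in all 5 libraries, while mt-Cytb reached 5182 ± 150.3 RPKM and mt-Nd1 4791 ± 361. The sequence of mt-Co2 and mt-Co3 is found in full in other annotated transcripts, that of mt-Atp6 to 99.2%, mt-Nd3 to 98.3% and mt-Nd4l to 98.0%. mt-Atp8, which shares none, overlaps mt-Atp6. Ribosomal protein genes, whose products are assembled into the same particle, had unequal values, such as 245 ± 8.83 RPKM for Rpl8 and 1.06 ± 0.259 for Rpl19. Of the 29 ribosomal genes, the 20 that share at least 20% of their sequence with other genes had a median of 4.39 RPKM and the other 9 a median of 51.9. Levels are therefore uncertain for genes with near-identical copies, which among the genes named here include the globin genes, Gapdh (47.8% shared), Mt2 (37.9%), Hspa8 (56.7%) and Igf2 (78.7%). The counted mitochondrial genes mt-Nd4 (62.4%) and mt-Co1 (51.3%) are uncertain too, and with them the mitochondrial share of the counts.

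**Figure D2:**
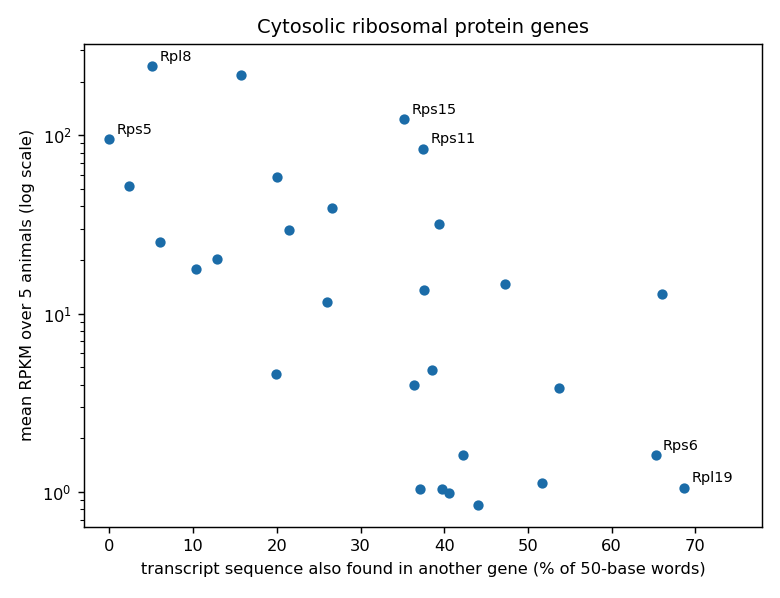
Mean RPKM of 29 cytosolic ribosomal protein genes (log axis) against the percentage of their sequence found in other annotated transcripts. Genes that share little sequence have a median of 51.9 RPKM and those that share at least 20% a median of 4.39.

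Genes induced by glucocorticoids, the adrenal stress hormones, differed between the animals more than genes of like abundance, with higher values in animals 3 and 5. Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903), a kinase gene induced by these hormones, stood at 32.9 and 35.2 RPKM in animals 3 and 5 and at 10.6, 12.5 and 14.9 in animals 1, 2 and 4. Its range between animals was 3.29-fold (edgeR quasi-likelihood test against the abundance trend, adjusted p = 8.49e-08). Nfkbia (2.55-fold, adjusted p = 0.000242), an inhibitor of NF-kappa-B, Ddit4 (2.05-fold), an inhibitor of mTOR signalling, Arrdc2 (2.68-fold) and Tsc22d3 (1.73-fold), which encodes the glucocorticoid-induced leucine zipper, had the same pair of animals highest. Of the 14 genes of the glucocorticoid list, 4 were called over all genes tested (Sgk1, Tsc22d3, Ddit4 and the lipid droplet gene Plin4) and 12 adjusted over the list alone. Here and below, counts adjusted over the list alone are not adjusted for the number of lists. The list moved together, with a mean log2 deviation of 0.33 in animal 3, 0.29 in animal 5, -0.36 in animal 2, -0.18 in animal 1 and -0.088 in animal 4 (permutation adjusted p = 0.000728). All 14 members lay above their own mean in animal 3 and below it in animal 2. In animal 2 the long nuclear RNA list, fixed as a sign of library quality, had its highest mean (0.17, against -0.025 in animal 3 and -0.017 in animal 5). Txnip, Arl4d, the clock gene Per1 and the glucose transporter gene Slc2a1 were also called and also highest in animals 3 and 5. The circadian clock list, which holds Per1, also moved together (permutation adjusted p = 0.00450), with mean log2 deviations of 0.071 in animal 3, 0.063 in animal 5, -0.0089 in animal 4, -0.034 in animal 1 and -0.091 in animal 2, the same order of animals as the glucocorticoid list. The mature oligodendrocyte list, a cell type that expresses several of these genes, lay at -0.091 in animal 3 and -0.061 in animal 5. Sgk1 and Nfkbia stayed past the threshold in all 16 alternatives, and Ddit4, Arrdc2 and Tsc22d3 did so without any 1 animal. With limma on recomputed RPKM the adjusted p was 0.0552 for Ddit4, 0.0641 for Arrdc2, 0.174 for Tsc22d3, 0.586 for Plin4, 0.244 for Txnip, 0.102 for Arl4d, 0.629 for Per1 and 0.533 for Slc2a1. With limma on deposited RPKM it was 0.240 for Tsc22d3, 0.175 for Plin4, 0.933 for Txnip, 0.124 for Arl4d, 0.933 for Slc2a1 and 0.941 for Per1, whose log2 ratio to the trend turned to -0.61, and with an edgeR prior that is not robust it was 0.0934 for Per1 and 0.0880 for Slc2a1. In the deposited RPKM, 80% of entries were divided by the total of another library, which adds spread between animals. Without animal 3 the adjusted p was 0.122 for Plin4, 0.0703 for Txnip, 0.0638 for Arl4d, 0.189 for Per1 and 0.0950 for Slc2a1. Without animal 2 it was 0.0577 for Plin4, 0.0577 for Per1 and 0.0559 for Slc2a1, and without animal 5 it was 0.0527 for Per1 and 0.0813 for Slc2a1.

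Transcripts of red blood cells and of hypothalamic peptide neurons and the transmitter genes Tph2 and Slc6a5 also differed between animals. The globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 and the haem synthesis gene Alas2 were highest in animal 3 and lowest in animal 5, with ranges of 3.41-fold to 3.89-fold (2.15-fold to 2.57-fold over the other animals without animal 3, and 1.74-fold to 2.44-fold without animal 5). They were 5 of the 7 tested genes of the erythroid list, both over all genes and adjusted over the list alone, and the globin genes share 58.0% to 87.9% of their sequence with other genes, so their split is uncertain. Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) stood at 162 RPKM in animal 3 and 42.5 in animal 5 (adjusted p = 4.85e-07). Oxt (ENSMUSG00000027301, chromosome 2, 130576173 to 130577054), which encodes oxytocin, ranged 4.63-fold (1.56-fold without animal 5) and its neighbour Avp, which encodes vasopressin, 2.32-fold (1.59-fold without animal 5), both lowest in animal 5. Gabrq, Irs4 and Baiap3 were also lowest in animal 5 and highest in animal 2, where the long nuclear RNA list, fixed as a sign of library quality, also had its highest mean (0.17). Tph2 (ENSMUSG00000006764, chromosome 10, 115078641 to 115185022), the enzyme of serotonin synthesis in neurons, ran from 0.389 RPKM in animal 1 to 3.27 in animal 2 (7.44-fold, or 4.07-fold without animal 2, adjusted p = 0.00179). Slc6a5 (ENSMUSG00000039728, chromosome 7, 49910146 to 49963856), the glycine transporter of brainstem and spinal neurons, had a range of 20.3-fold (4.22-fold without animal 4 and 8.93-fold without animal 5), with 3.58 RPKM in animal 4 and 0.158 in animal 5 (adjusted p = 3.64e-07). The inhibitory receptor gene Glra1 had 3.56 and 1.01 in those animals (adjusted p = 0.0734). It and Slc6a5 were the only 2 tested members of the brainstem and spinal cord list, too few for the list test. Without animal 5 the adjusted p was 0.822 for Oxt, 0.341 for Avp, 0.660 for Alas2, 0.170 for Hba-a1, 0.161 for Hba-a2, 0.263 for Gabrq and 0.142 for Baiap3. Without animal 3 it was 0.175 for Alas2, 0.211 for Hba-a1 and 0.677 for Hba-a2, without animal 2 0.0890 for Irs4 and 0.0616 for Gabrq, without animal 1 0.0779 for Avp and without animal 4 0.0679 for Slc6a5. With limma on recomputed RPKM the adjusted p was 0.0641 for Slc6a5, 0.115 for Tph2, 0.607 for Irs4, 0.247 for Baiap3, 0.533 for Gabrq, 0.0510 for Avp and 0.244 for Alas2, and with limma on deposited RPKM it was 0.527 for Baiap3 and 0.0515 for Gabrq. With an edgeR prior that is not robust it was 0.0603 for Oxt, 0.0829 for Hba-a1, 0.0962 for Hba-a2, 0.116 for Alas2, 0.0880 for Avp and 0.0545 for Gabrq.

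Other called genes had a single high or low animal or a pair of them. The striatal adenosine receptor Adora2a was highest in animal 1 (24.4 RPKM against 15.6 to 17.9 in the other animals), the activity-induced genes Npas4 in animals 1 and 2 and Btg2 in animal 2, the presynaptic calcium sensor Syt2 in animal 4, and the snoRNA Snord49a in animal 5. Sparc, a secreted matrix glycoprotein, and Gpx3 were lowest in animal 5. In total 45 of 14770 genes tested varied more than the abundance trend at an adjusted p of 0.05 (802 unadjusted), with a median range of 2.06-fold against 1.19-fold over all genes tested. Animal 5 had the lowest value for 22 of the 45 and animal 2 for 12. Without any 1 animal, 8 of the 45 stayed past the threshold in every fit (Sgk1, Hbb-bs, Nfkbia, Ddit4, Hbb-bt, Arrdc2, Tsc22d3 and Tph2), and of these Sgk1, Hbb-bs, Nfkbia and Hbb-bt in all 16 alternatives. The count depends on the method, with 249 genes called with no low-count filter, 101 as DESeq2 dispersion outliers, 19 with an edgeR prior that is not robust, 27 with limma on deposited RPKM and 10 with limma on recomputed RPKM. The number called was 26 without animal 3 and 18 without animal 5, and the adjusted p was 0.990 for Adora2a and 0.102 for Npas4 without animal 1, 0.942 for Btg2 without animal 2, 0.0539 for Syt2 without animal 4, and 0.579 for Snord49a, 0.871 for Sparc and 0.733 for Gpx3 without animal 5. Adora2a without animal 2 had 0.0559, Gpx3 without animal 2 0.0780 and Sparc without animal 3 0.0671. With limma on recomputed RPKM the adjusted p was 0.557 for Adora2a, 0.311 for Npas4, 0.266 for Btg2, 0.533 for Syt2, 0.490 for Sparc and 0.174 for Gpx3, and with limma on deposited RPKM it was 0.933 for Adora2a, 0.312 for Npas4, 0.158 for Btg2, 0.194 for Syt2, 0.531 for Snord49a and 0.691 for Sparc. With an edgeR prior that is not robust it was 0.122 for Adora2a, 0.0545 for Npas4, 0.115 for Sparc and 0.0880 for Gpx3, and Adora2a kept its call in 8 of 16 alternatives. Gapdh was called too, but shares sequence with its pseudogenes and is uncertain (adjusted p 0.124, 0.122 and 0.302 without animals 1, 3 and 5, and a call kept in 7 of 16 alternatives).

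**Figure D3:**
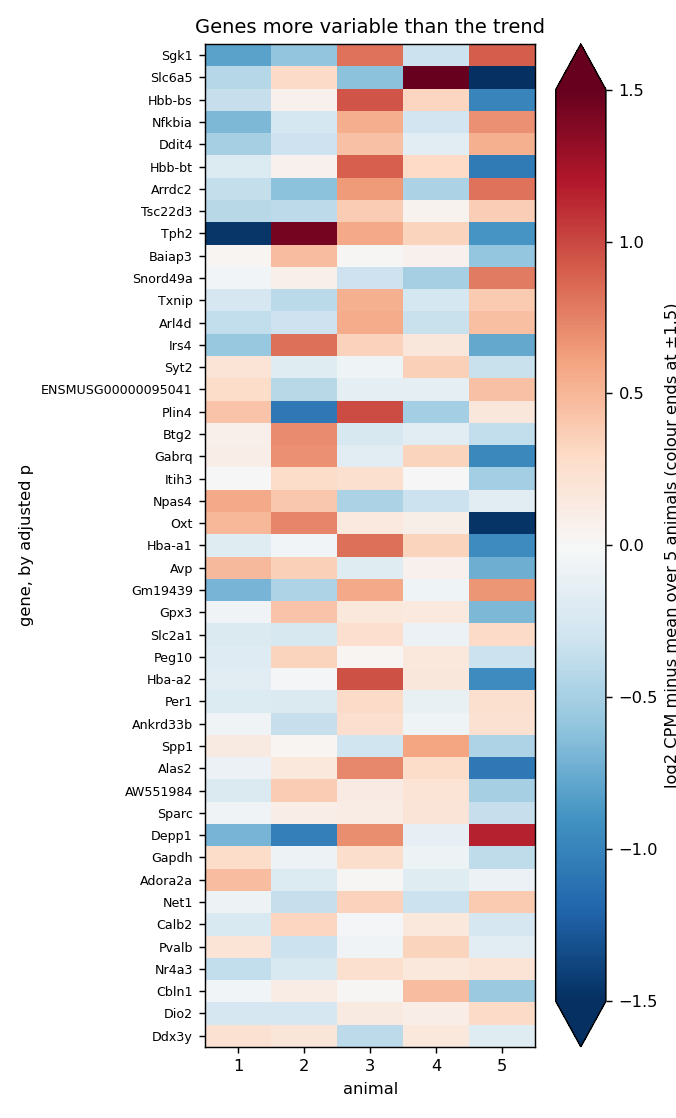
Log2 deviation of CPM (counts scaled to library depth) from the gene's own mean in each of the 5 animals, for genes called more variable than the abundance trend, with colour ending at ± 1.5. Sgk1, Nfkbia, Ddit4 and Arrdc2 are high in animals 3 and 5, globin genes in animal 3, and Slc6a5 in animal 4.

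Fixed lists of markers and pathways were tested for a joint spread between animals, which a few members can carry. The neuropeptide list passed that test, although only 11 of its 20 members lay above their mean in its highest animal. Monoaminergic neuron genes were lowest in animals 5 and 1 (mean log2 deviations -0.56 and -0.43) and highest in animal 2 (0.49), with Tph2 called over all genes and 5 of 6 members adjusted over the list alone. The dopamine synthesis gene Th and the vesicular transporter gene Slc18a2 had deviations of 0.33 and 0.40 in animal 2 and -0.49 and -0.44 in animal 5. Hypothalamus genes were highest in animal 2 (0.38) and lowest in animal 5 (-0.50), with 2 of 11 members called over all genes and 4 adjusted over the list alone. Cerebellum genes were all highest in animal 4 (10 of 10 members, list mean 0.36), with Cbln1, a synapse organiser of granule cells, called over all genes and 3 members adjusted over the list alone. Gabra6 and Pcp2, markers of cerebellar granule and Purkinje cells with too few counts for the test, had 1.65 and 0.878 RPKM in animal 4 and no more than 0.0300 and 0.166 in any other animal. Striatum genes were highest in animal 1, where 13 of 16 members had their highest value (list mean 0.22), with 1 called over all genes and 10 adjusted over the list alone. Mature oligodendrocyte genes were highest in animal 4 (14 of 15 members, list mean 0.20), with 0 called over all genes by edgeR at an adjusted p of 0.05 and 8 adjusted over the list alone. Antigen presentation and interferon response genes were also highest in animal 4 (0.27 and 0.26), as were heat shock genes (0.23). The mitochondrially encoded list was highest in animal 4 too (0.097, 7 of 7 members) and lowest in animal 5 (-0.083). Olfactory bulb genes were highest in animal 2 (0.24) and cholinergic neuron genes lowest in animal 5 (-0.33). Long nuclear RNAs, a list fixed as a sign of library quality, were highest in animal 2 as well (0.17, against -0.082 to -0.017 in the others, permutation adjusted p = 0.00170), as were the hypothalamus, monoaminergic neuron and olfactory bulb lists, with 0.481 without animal 2 and 0.245 with no low-count filter. Y-linked genes were lowest in animal 3 (-0.23), with Ddx3y called over all genes and 2 of 4 members adjusted over the list alone. Of the 51 lists with at least 4 tested members, 33 had a spread between animals beyond that of random lists of the same size and abundance at a permutation adjusted p of 0.05, which describes these 5 libraries only, since genes are not independent replicates. Some lists share members, such as Oxt and Avp (hypothalamus and neuropeptides) and Th (monoaminergic neuron and olfactory bulb). The 33 calls are therefore not all separate results. In 23 lists the members also or instead varied more than random genes of like abundance, 22 of them among the 33. The erythroid, striatum, hypothalamus, monoaminergic neuron, circadian clock, glucocorticoid and mitochondrially encoded lists kept their call under every alternative run. For the erythroid list only 15 of 17 alternatives could be run. Without its called members, or without those that share sequence, fewer than 4 tested members remained, so the call was not tested without the globin genes. The mitochondrially encoded list was run in 16. Without animal 4 the number of lists that moved together was 19 and of those with variable members 15, and the permutation adjusted p was 0.0892 for cerebellum, 0.166 for mature oligodendrocytes, 0.401 for antigen presentation, 0.506 for interferon response and 0.0892 for heat shock. It was 0.200 for olfactory bulb without animal 2, 0.0957 for cholinergic neurons without animal 5 and 0.208 for Y-linked genes without animal 3, and Cbln1 had an adjusted p of 0.320 without animal 4 and 0.547 without animal 5, and Ddx3y 0.721, 0.0921, 0.0554 and 0.0551 without animals 3, 1, 2 and 5. Of 16 alternatives Cbln1 kept its call in 8 and Ddx3y in 4, with an adjusted p of up to 0.547 and 0.727.

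**Figure D4:**
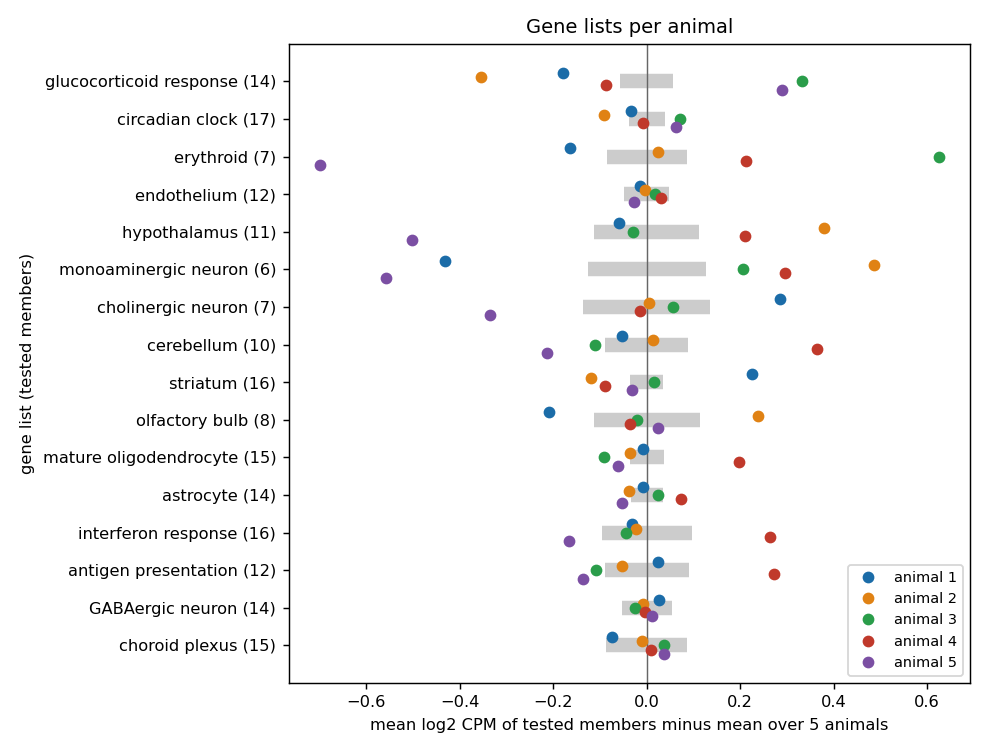
Mean log2 deviation of 16 of the fixed gene lists in each of the 5 animals (points), with a grey bar from minus to plus the 95th percentile of the SD of random lists matched on size and abundance. The erythroid, monoaminergic, hypothalamus and glucocorticoid lists spread widest, and the GABAergic neuron and endothelium lists lie near zero in all 5 animals.

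Other lists had means that stayed close in the 5 animals, which can also occur when their members move in opposite directions. Endothelial genes had a spread of 0.023 (SD of the list mean, log2), inhibitory neuron genes 0.020, amyloid and tau genes 0.014 and extracellular matrix genes 0.0081, all below the median of random lists. Single matrix genes did not vary less than others. Their median log2 ratio to the abundance trend was 0.31, against -0.18 for random lists (permutation adjusted p = 0.140). The endothelial, inhibitory and matrix lists each held 1 called gene (Slc2a1, Pvalb and Sparc), and Pvalb, a calcium-binding protein of fast-spiking interneurons, was lost in all 5 leave-one-out fits (adjusted p 0.0510 to 0.217) and kept its call in 5 of 16 alternatives (up to 0.802). Choroid plexus genes (0.046), microglial genes (0.043), hippocampal genes (0.046), thalamic genes (0.034), proteasome genes (0.015) and nuclear complex I genes (0.026) also missed the threshold, as did pan-neuronal genes (0.035). These misses do not show equal values, since on simulated data lists raised 1.1-fold in 1 or 2 animals were called in 56.0% of cases. The lowest ratios to the abundance trend among well-counted genes belonged to Ppp1r21, Plppr4, Rgs6, Ap1b1 and Atrx, with ranges of 1.01-fold. The adaptor gene Ap1b1 stood at 52.9 ± 0.592 RPKM and the chromatin remodeller Atrx at 11.6 ± 0.0942. By edgeR 0 genes varied less than the trend at an adjusted p of 0.05 (739 unadjusted), limma called 0 on log2 CPM and on log2 RPKM, and edgeR with no low-count filter called 25. Typical variation between animals, the common biological coefficient of variation, was 4.95% (jackknife standard error 0.499).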

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

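Of the tests in this part, those on the oligodendrocyte share and on the depth of mitochondrial genes were chosen only after the result was seen. The called genes had been seen before the other tests were chosen, and 2 tests of erythroid genes, on the amount of blood and on vascular share, were dropped after the list results were seen. A library counted as standing apart when its gap to the nearest other library, as a share of the range of the 5, passed Dixon's limit, which chance passes in about 1 in 20 groups. Of 304 groups of values tested, 16 passed it, close to that share, with 3, 5, 2, 4 and 2 of them in animals 1 to 5. None of the 5 library measures, the 45 called genes and the 28 gene pairs did. Values below are the difference of that animal from the median of the other 4 on the log2 scale.

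Among the gene lists, mature oligodendrocyte genes stood apart in animal 4 (0.25), long nuclear RNAs in animal 2 (0.21), voltage-gated ion channels in animal 1 (0.089) and cytosolic ribosome genes in animal 3 (-0.077). Among genes, the ependymal Ccdc153 stood apart in animal 2 (0.66), the photoreceptor arrestin gene Sag in animal 3 (0.58) and the vesicular acetylcholine transporter gene Slc18a3 in animal 5 (-1.13). The striatal signalling gene Ppp1r1b stood apart in animal 1 (0.35), and the small heat shock gene Cryab (0.36) and the antigen-presenting gene H2-K1 (0.60) in animal 4. Smaller differences were those of Rprm (-0.18) and Clu (-0.061) in animal 2, Atp5b in animal 4 (0.060), Psmb1 in animal 5 (-0.088), Xiap in animal 2 (-0.021) and Plppr4 in animal 1 (-0.016).

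The spread of glucocorticoid-responsive genes was weighed against 3 technical explanations here and, as a hypothesis, against time of day. A larger share of oligodendrocytes in animals 3 and 5, the 2 highest for the glucocorticoid list, is argued against, since their list lay at -0.091 and -0.061 there. Its mean in these animals plus 2 standard errors was -0.048. These errors run over the 15 member genes, not over animals, and genes are not independent replicates. The SD of the oligodendrocyte list was 38.0% of the SD of the glucocorticoid list, above the limit of 25% set earlier. A different share of endothelial cells is argued against by a spread of their list of 7.82% of that SD, whereas mural cells, not part of that test, stay open (list SD 0.080 against 0.30, with means of -0.017 in animal 3 and 0.029 in animal 5). A gene length bias is argued against, since correction for length left the spread at 101% of its value. What else differed between the animals stays open, and no label records it.

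The spread of hypothalamic genes was not removed by a gene length correction, which left it at 99.7% of its value. Without Oxt and Avp, the other 9 members still moved together, with an SD of 0.29 against 0.13 for the 95th percentile of random lists (percentile 100 of 10000 random lists). Their means were 0.34 in animal 2, 0.24 in animal 4, -0.031 in animal 3, -0.18 in animal 1 and -0.37 in animal 5, whereas Oxt and Avp themselves had 0.49 and 0.48 in animal 1 and 0.091 and 0.070 in animal 4. The values of these 9 members are in line with a different amount of hypothalamus in the dissected hemispheres, which may account for the 9 other members, as a hypothesis, while Oxt and Avp stay open. No biological explanation was tested.

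Genes with near-identical copies were listed at 0 or at low values. Low depth or poor capture of mitochondrial RNA is argued against, since the mitochondrial genes next to those listed at 0 had at least 34488 counts in every library. Across the 29 ribosomal protein genes, which are not independent replicates, mean RPKM fell with shared sequence (Spearman rho = -0.67, permutation p = 0.0001, Pearson r = -0.49), which is in line with reads that match more than 1 place not having been counted, a step that no source used here states. mt-Atp8 shares no sequence with other annotated transcripts, and copies outside the annotation were not searched. No biological explanation was tested.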

How the results depend on the processing

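Of the alternatives in this part, limma on recomputed RPKM, the bias-adjusted deviances, the deposited RPKM for detection, pairs and levels, and the lists without called or sequence-sharing members were chosen only after the data were seen. No paired analysis was possible because the samples form 1 group. The number of more variable genes was 45 and moved to 249 with no low-count filter (45 of them shared), 19 with a prior that is not robust, 27 with limma on deposited RPKM, 10 with limma on recomputed RPKM, 18 at a threshold of 0.01 and 101 with DESeq2 dispersion outliers (45 shared). It was 18 to 44 with 1 library left out and 34 to 45 in the other settings. The number of less variable genes was 0 and 25 with no filter, 0 to 0 with 1 library left out. The coefficient of variation, 4.95%, was 4.62% to 5.39% with 1 library left out. Lists that moved together, 33, were 19 to 30 with 1 library left out and 27 to 34 otherwise, and lists with variable members, 23, were 15 to 25 and 23 to 26. Detected genes, 13039, were 13003 to 13052 with 1 library left out and 20473 at an RPKM of 0.1. The share of the 100 most abundant genes, 15.9%, was 15.8% to 15.95% with 1 library left out, 26.6% of summed RPKM and 13.5% without mitochondrial genes. The mitochondrial share, 3.68%, was 3.60% to 3.73% with 1 library left out and 14.3% of summed RPKM. Pairs with 1 order, 26, were 26 to 27 with 1 library left out and 23 to 28 otherwise. Directions turned for Per1 with limma on deposited RPKM (log2 ratio to trend -0.61), for member variation (median log2 ratio to trend) of meningeal fibroblast genes without replicate 2 and of heat shock and interferon response genes without replicate 4, with ranges of -0.079 to 1.12, -0.12 to 1.096 and -0.055 to 0.87 with 1 library left out, and on counts without length for Gria2 against Gria1 (0.19), Aldoc against Aldoa (-0.17), Slc2a3 against Slc2a1 (0.74), Drd1 against Drd2 (0.76) and 1 pair not named here (-0.51). The cause was not tested, except that counts without length leave out the length term, leaving out a library leaves fewer samples, and a stricter threshold calls fewer genes. In the deposited RPKM, 80% of entries were divided by the total of another library. Their median SD of log2 values between animals was 0.158, against 0.0648 with each library's own total. Results with limma on deposited RPKM carry this added spread. Limma on recomputed RPKM does not carry it and called 10 genes. Depth limits genes with few counts. The filter leaves out those with the fewest, but genes with low counts remain among those tested, such as Depp1 at a mean of 2.42 CPM. On simulated counts, 2-fold changes were called in 72.8% of cases over all genes tested and in 90.4% above 4 CPM.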

Other observations

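The test on time of day was chosen only after the result was seen. Genes of neighbouring tissues and of white cells had mostly low values. The pituitary hormone genes Gh and Prl had means of 0.412 ± 0.255 and 0.0292 ± 0.0400 RPKM (SD, n = 5), whereas Pomc, which hypothalamic neurons also express, had 2.87 ± 1.59. Acta1 of the skeletal muscle list stood at 5.70 ± 0.745 and Gnal, an olfactory epithelium gene that striatal neurons also express, at 46.6 ± 1.91. The neutrophil genes S100a9 and S100a8 stood at 1.72 ± 0.687 and 0.911 ± 0.626, the T cell receptor gene Trbc2 at 4.51 ± 0.703 and the B cell gene Cd79b at 0.196 ± 0.0529. The proliferation gene Mki67 had 0.174 ± 0.0236 and Dcx, a marker of immature neurons, 2.98 ± 0.293. The inflammation genes Lcn2 and Serpina3n had 0.111 ± 0.0671 and 7.35 ± 0.581. Slc6a4, the serotonin transporter gene, had too few counts for the test and ran from 0.0335 RPKM in animal 5 to 1.74 in animal 2, the animal that was also highest for Tph2.

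Erythroid transcripts kept nearly fixed ratios to each other. The SD over the 5 animals of log2 CPM was 0.72 for Hbb-bs, and the SD of the log2 ratio to Hbb-bs was 0.084 for Hbb-bt, 0.12 for Hba-a1, 0.12 for Hba-a2 and 0.19 for Alas2. Bpgm, a member of the erythroid list that brain cells also express, had a log2 deviation of 0.017 in animal 3, against 0.95 for Hbb-bs.

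Animals 3 and 5 were the 2 highest for 15 of the 45 called genes, and for 9.74% of all genes tested. This pair was singled out after its values were seen, and the 45 genes are not independent of each other.

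A hypothesis is that the animals died at different times of day, which would move glucocorticoid-responsive genes, since the hormone follows a daily rhythm. If so, clock output genes would spread with them. A clock score of 10 genes, with Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per2, Per3 and Ciart on 1 side and Arntl and Npas2 with the opposite sign, had an SD of 0.052, which is 17.3% of the SD of the glucocorticoid list, below the limit of 25% set for it. The score was 0.069 in animal 3, 0.015 in animal 1, 0.011 in animal 5, -0.023 in animal 4 and -0.072 in animal 2. Its highest and lowest animals were those of the glucocorticoid list, but the order between them was not. The fixed circadian clock list moved together (permutation adjusted p = 0.00450) and ranked the animals in the same order as the glucocorticoid list, with an SD of 0.068 against 0.30. It holds Per1, called with that pattern, and takes genes of opposite phase with the same sign. It kept its call in all 17 alternatives, among them the list without called members (permutation adjusted p of at most 0.0439). How far each group of genes would move over the same hours was not measured, so these SDs cannot decide the question. Time of day stays open.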
